A study of Mus musculus with 8 samples.

How the data were processed

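RNA sequencing of left ventricles was examined in 8 libraries from female C57BL/6J mice aged 18 to 22 months. The LFD_control group (n = 4) had a control diet and saline. The HFD_AngII group (n = 4) had a high fat diet for 12 weeks and received angiotensin II, the pressor peptide hormone, by implanted osmotic pump for the last 4 weeks, after 8 weeks of diet. The diet label of the control group gives a low fat diet, whereas the treatment protocol speaks of a standardized chow, and which of these was fed could not be settled here. Total RNA was extracted with Trizol and libraries were made with a stranded poly(A) mRNA kit, per the labels' protocols. The series title also names liraglutide and dapagliflozin, and samples with these drugs were not analysed here.

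The authors deposited 1 table of read counts per gene, whole numbers that were not normalized. STAR 2.4.2a, HTSeq 0.6.1 and the mm10 genome are named in the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of genes that overlap a gene on the opposite strand are uncertain. The table held 38293 gene identifiers, and its columns were matched to samples by the sample descriptions in the labels. No row held a total or a count of unassigned reads. Of the identifiers, 36345 matched the GENCODE M21 annotation of GRCm38 (mm10), which gave the symbols, coordinates (1-based), exonic lengths and GC content.

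Library totals ran from 12105043 to 15044886 counts. Genes were kept by edgeR's filterByExpr with its default minimum count of 10, which left 13460 genes with 99.9% of the counts and removed 24833, of which 16263 had no counts. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust=TRUE, then glmQLFTest) in R 4.3.3, with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. All adjusted p-values of single genes below come from this test, with a threshold of 0.05. Log2 fold changes are HFD_AngII minus LFD_control, and their standard error (SE) was taken from the quasi-likelihood F. Levels are CPM, read counts scaled to a common library total, after TMM, given as mean ± SD over 4 libraries.

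Before the data were examined, 54 gene lists were fixed, 32 of pathways and 22 of cell type markers, together with 21 single genes, the tests, the rule for naming genes and the first set of other settings. Of 1055 list entries 1049 matched the annotation, 2 of them through a synonym. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted separately over pathway and cell type lists. Camera compares the genes of a list with all other genes. Member counts are given over all genes tested and, in brackets, adjusted over the list alone. The lung epithelial (1 tested gene) and thymus (2 tested genes) lists were too small to test. Named genes are the single genes fixed beforehand, the 10 largest rises and 10 largest falls among genes past the threshold with a mean CPM of at least 2 and no overlap between the groups (predicted genes and pseudogenes passed over), and up to 4 members of each list with the smallest p. Some genes under this rule are not reported here. Other genes are said to have been chosen after their values were seen.

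Measures of single libraries were compared by two-sided exact permutation tests over all 70 assignments, for which the smallest possible p is 0.0286. The labels state 4 samples per condition without saying that each is a separate animal, so p-values measure the spread between these samples. No replicate pair looked like the same library deposited again, since the Spearman correlations within groups ran from 0.986 to 0.992 and the chi-square per gene from 7.22 to 17.8.

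The procedure was tested on simulated data with the means, dispersions and library sizes of this comparison, 13460 genes and 200 genes changed per draw. A first draw gave 20 false calls among 177 with edgeR (11.3%), a share above the nominal 5%. For that reason 5 more draws were added, and the first was kept. Over the 6 draws, edgeR made 65 false calls among 1037 (6.27%), with 1.91% to 11.3% per draw, limma-voom 56 among 1017 (5.51%), and DESeq2 134 among 1128 (11.9%). EdgeR recovered 56.3% of genes changed 1.5-fold, 78.0% at 2-fold, 92.7% at 3-fold and 97.0% at 4-fold, none with the wrong sign. Camera called the changed list in 6 of 6 draws and 0 of 120 unchanged lists, with edgeR, limma-voom and DESeq2 alike; the simulated genes were independent of each other, so this says nothing about correlated lists.

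The settings fixed beforehand were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, a fit without robust=TRUE, the replicate number as a block, 1 surrogate variable (sva 3.50.0), each library left out in turn, camera with an estimated correlation, and fry. Chosen after seeing the data were a correction of each library for exonic length and GC content, the levels of the atrial or the erythroid list as a covariate, a fit without HFD_AngII 3 and 4, and a fit without LFD_control 1, HFD_AngII 3 and HFD_AngII 4.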

Results

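Gene expression was measured by RNA sequencing in the left ventricle of aged female mice. The LFD_control group (control diet and saline) and the HFD_AngII group (high fat diet with angiotensin II) had 4 libraries each. The totals were 14006815, 13328409, 12105043 and 12923548 counts in LFD_control 1 to 4. They were 12709997, 14997839, 15044886 and 13442349 counts in HFD_AngII 1 to 4, a difference between groups within the spread between libraries (exact permutation p = 0.229, n = 4 per group). Mitochondrially encoded genes took 19.6 ± 1.33% of counts in LFD_control and 19.3 ± 1.51% in HFD_AngII (SD, n = 4; exact permutation p = 0.886). The series title describes mice in which several insults were combined to model heart failure without loss of ejection fraction, and the comparison asks how the ventricle's transcripts differ under the combined diet and hormone. Diet and angiotensin II were changed together, so neither can be assigned a difference.

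In HFD_AngII, 35 of 43 interstitial matrix genes and 12 of 17 genes known to respond to load in cardiomyocytes rose, while 43 of 49 nuclear genes of the mitochondrial respiratory chain, 12 of 24 cardiac ion channel genes and 4 of 6 platelet genes fell. As lists these 5 passed camera with a preset correlation between genes, and none of them did with an estimated correlation (adjusted p = 0.361, 0.361, 0.583, 0.361 and 0.575 with an estimated correlation, in that order). Directional fry asks whether a list shifted, not whether it shifted more than the other genes. Its adjusted p was 0.00348, 0.00348, 0.0319, 0.0101 and 0.00917 for the 5 lists, in the same order. Acta1, the skeletal alpha-actin that is re-expressed in loaded hearts, rose from 374 ± 59.7 to 1608 ± 603 CPM (SD, n = 4), a log2 fold change of 2.10 (SE 0.26, adjusted p = 0.00306). Col1a1, a chain of type I collagen, rose from 150 ± 33.5 to 329 ± 22.8 CPM, a log2 fold change of 1.13 (SE 0.13, adjusted p = 0.000662). Sdha, a subunit of respiratory complex II, fell by 0.43 on the log2 scale (SE 0.09, adjusted p = 0.00676). Of 13460 genes tested with edgeR, 2080 (15.5%) passed an adjusted p of 0.05, with 1074 higher and 1006 lower in HFD_AngII. At least a 1.5-fold change was seen in 432 of the higher and 322 of the lower genes, and at least a 2-fold change in 179 and 98. The 2 groups did not overlap in 2721 tested genes (20.2%, against 2.86% by chance).

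The number of calls depended on single libraries. It was 922 without HFD_AngII 4, 1130 without LFD_control 4 and 1208 without LFD_control 1, and the number of lower genes was 626 without HFD_AngII 1. Without both HFD_AngII 3 and 4 it was 325, in a fit chosen after seeing the data. With total-count scaling 63.1% of the calls were higher, against 51.6% with TMM. Fold changes also followed gene length. The median log2 fold change ran from -0.13 in the tenth of genes with the shortest exonic length to 0.15 in the tenth with the longest, and the correlation with length across genes, which are not independent replicates, was 0.25 (Spearman's rho). The rho between a library's deviations and gene length was -0.15 ± 0.06 in LFD_control and 0.14 ± 0.08 in HFD_AngII (SD, n = 4, exact permutation p = 0.0286, the smallest possible). After a correction for length and GC content, 1821 genes passed, 1526 of them shared with the 2080. Of the 1821, 814 (44.7%) were higher and 1007 lower. The correction also moved the median log2 fold change of all tested genes from 0.00075 to -0.021. A shift of all genes changes the balance of higher and lower calls by itself. The change in balance can therefore not be put down to the length trend.

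**Figure D1:**
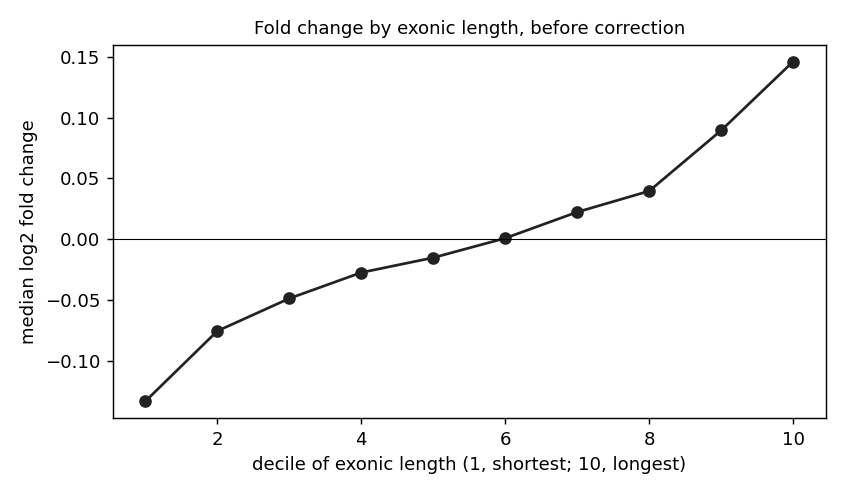
Median log2 fold change (vertical axis, HFD_AngII minus LFD_control) of tested genes in 10 equal groups by exonic length (horizontal axis, 1 the shortest), before any correction. The median lies at -0.13 in the shortest group and at 0.15 in the longest.

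Of the 52 gene lists tested, 15 differed from the other genes by camera, 9 with higher and 6 with lower values in HFD_AngII. None of these calls held when the correlation between genes was estimated from the data, and the adjusted p with an estimated correlation is given beside each.

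**Figure D2:**
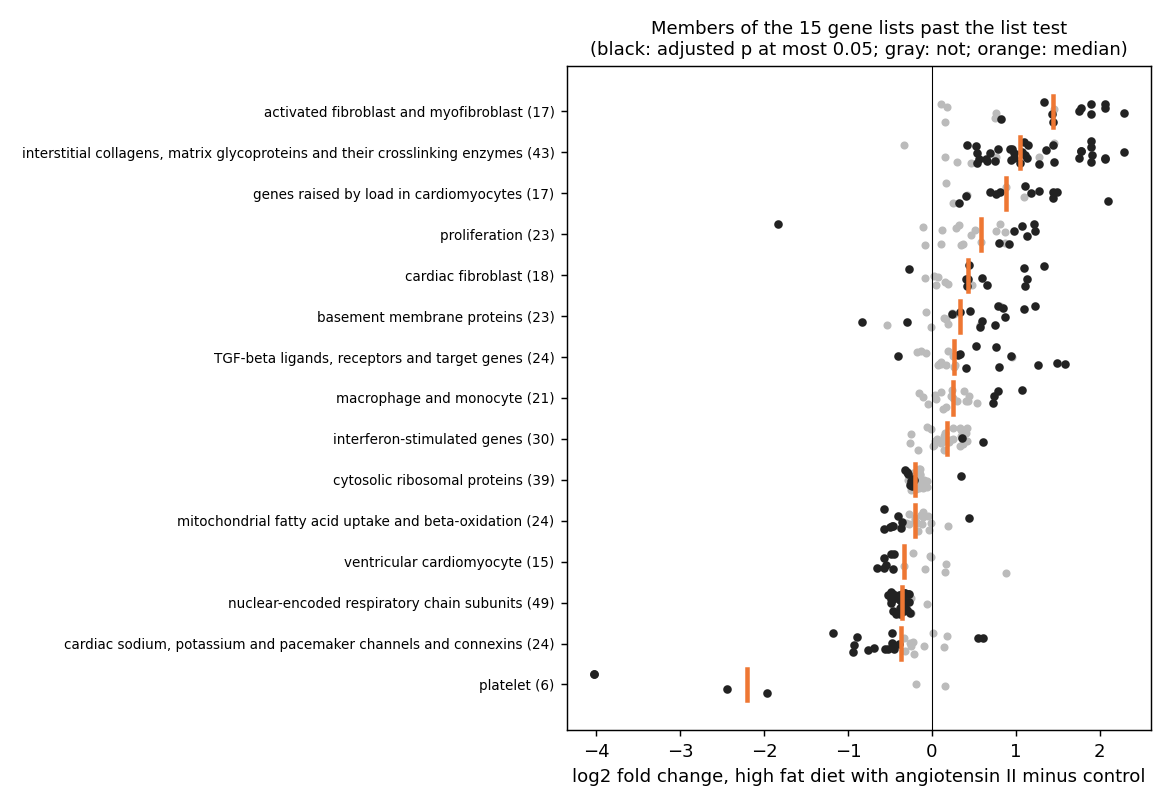
Log2 fold change (horizontal axis, HFD_AngII minus LFD_control) of each tested member of the 15 gene lists past camera, with the number of members in brackets. Black points passed an adjusted p of 0.05, gray points did not, and the orange bar is the median, from 1.45 for activated fibroblast genes to -2.21 for platelet genes.

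Interstitial matrix genes formed the list with the smallest camera p. Of 43 tested members 35 rose, 0 fell and 8 did not pass (38 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 1.05 (camera adjusted p = 6.93e-25; adjusted p = 0.361 with an estimated correlation). Col3a1, the chain of type III collagen, rose from 292 ± 67.8 to 626 ± 85.5 CPM (log2 fold change 1.10, SE 0.17, adjusted p = 0.00314). Postn, a matrix protein of activated fibroblasts, rose from 117 ± 41.2 to 437 ± 127 CPM (1.90, SE 0.30, adjusted p = 0.00836). Timp1, an inhibitor of matrix metalloproteinases, rose by 1.78 (SE 0.41, adjusted p = 0.0302), a call lost without LFD_control 1, 3 or 4 or HFD_AngII 1 or 4 and without a filter on low counts. Col12a1 rose by 1.91, Col5a2 by 1.36, Col16a1 by 0.93 and Col6a3 by 0.75 on the log2 scale. Without both HFD_AngII 3 and 4 the list had 22 members past the threshold and the basement membrane list 3. Basement membrane genes had 11 higher and 2 lower of 23 (13 and 3 adjusted over the list alone; median 0.34, camera adjusted p = 4.93e-05; adjusted p = 0.361 with an estimated correlation). Col4a1 rose by 0.87, Col4a2 by 0.78, Col4a3 by 1.23 and Lamc1 by 0.60. Col4a1 and Col4a2 overlap on opposite strands, so their counts may share reads if the counting ignored strand.

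Activated fibroblast markers rose in 11 of 17 (12 adjusted over the list alone), with 0 lower and a median of 1.45 (camera adjusted p = 2.22e-09; adjusted p = 0.575 with an estimated correlation). Thbs4, Lox and Meox1, a transcription factor of activated fibroblasts, rose by 1.89, 2.06 and 1.34. General cardiac fibroblast markers rose in 10 and fell in 1 of 18 (11 and 1 adjusted over the list alone; median 0.43, camera adjusted p = 4.56e-05; adjusted p = 0.575 with an estimated correlation). Of these 18, 12 were in no matrix, basement membrane, activated fibroblast or TGF-beta list. Among those 12, 5 rose and 1 fell, with a median of 0.28. The remaining markers were shared with those lists, so the results of these lists are not independent of each other. Mfap5 rose by 1.34 and Pdgfra, a growth factor receptor of fibroblasts, by 0.59. TGF-beta ligands, receptors and targets rose in 10 and fell in 1 of 24 (13 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 0.000129; adjusted p = 0.455 with an estimated correlation). Tgfb2 rose by 1.49, Tgfb3 by 0.80, the receptor Tgfbr1 by 0.52 and the target Ccn2 by 1.27. The TGF-beta list had 5 members past the threshold without LFD_control 4 and 7 without HFD_AngII 4, in place of 11. Without both HFD_AngII 3 and 4 the numbers past the threshold were 2 for activated fibroblast, 6 for fibroblast and 4 for TGF-beta genes.

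Genes raised by load in cardiomyocytes rose in 12 of 17 (12 adjusted over the list alone), with 0 lower and a median of 0.89 (camera adjusted p = 8.99e-10; adjusted p = 0.361 with an estimated correlation). Ankrd1, a stretch-responsive protein of the sarcomere and nucleus, rose from 1399.7 ± 97.2 to 3799.9 ± 775 CPM (log2 fold change 1.44, SE 0.14, adjusted p = 0.00019). Xirp2 rose by 1.45, Enah by 1.12 and Ankrd23 by 0.81. The count of 12 was 6 without LFD_control 1 and HFD_AngII 3 and 4. The natriuretic peptide genes did not pass. Nppa was at 366 ± 196 CPM in LFD_control and 786 ± 219 in HFD_AngII (log2 fold change 1.10, SE 0.56, adjusted p = 0.24), and Nppb had a log2 fold change of 0.89 (SE 0.36, adjusted p = 0.15). Nppb did pass in limma-voom, with the replicate block and with a surrogate variable, and Nppa without LFD_control 1 and HFD_AngII 3 and 4. The Nppa value lay beside low atrial marker genes in LFD_control 1 and HFD_AngII 3 and 4. Sln, an atrial gene named after its values were seen, was at 2.89 CPM in LFD_control 1 and 32.4 to 48.3 in the other LFD_control libraries. With the atrial list as a covariate, a setting chosen after seeing the data, Nppa had a log2 fold change of 1.20 and did not pass. Myh7, the slow myosin heavy chain, had a log2 fold change of 0.25 (SE 0.70, adjusted p = 0.851) whose sign changed without HFD_AngII 2 (-0.21) or HFD_AngII 3 (-0.05), and Myh6, the fast one, had -0.22 (SE 0.10, adjusted p = 0.136) and passed in DESeq2. Both overlap annotated antisense genes.

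**Figure D3:**
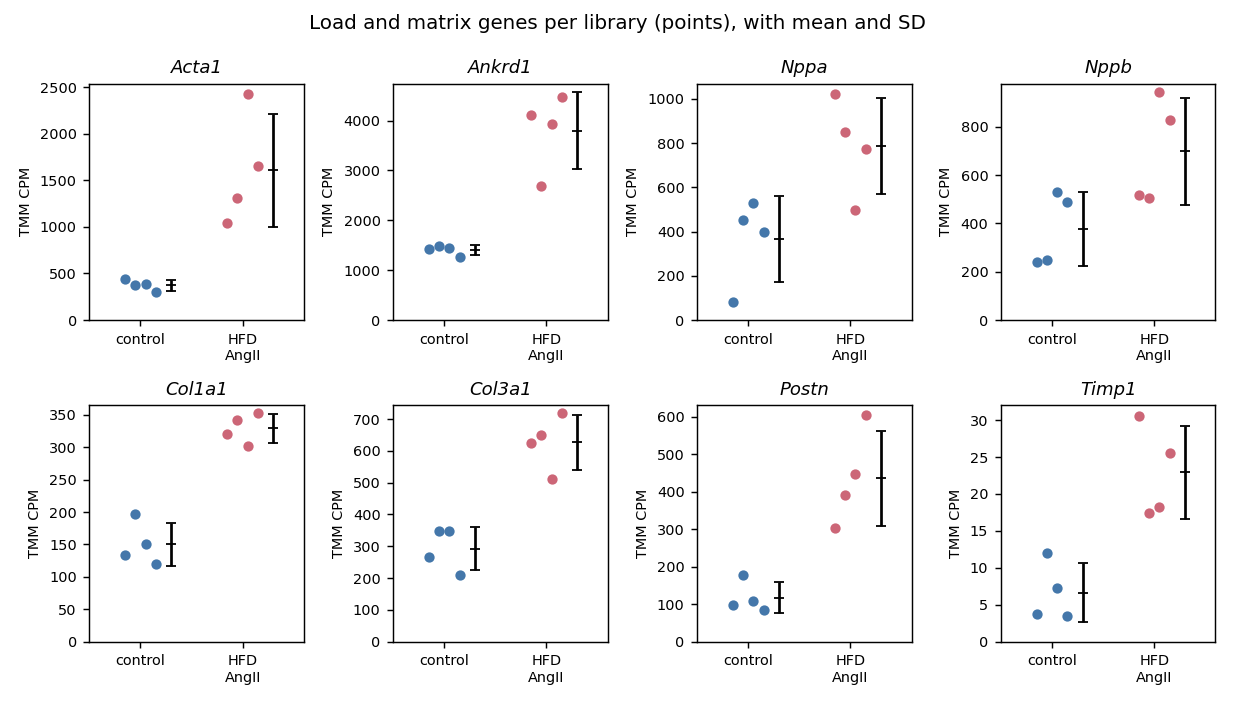
CPM after TMM scaling (vertical axes, each from 0) of 8 genes in the 4 LFD_control (blue) and 4 HFD_AngII (red) libraries, with bars for the mean and SD beside the points. Acta1, Ankrd1, Col1a1, Col3a1, Postn and Timp1 rose without overlap between groups, and Nppa (adjusted p = 0.24) and Nppb (adjusted p = 0.15) did not pass.

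Nuclear-encoded respiratory chain genes were lower as a group. Of 49 members 43 fell, 0 rose and 6 did not pass (48 lower adjusted over the list alone), with a median of -0.36 (camera adjusted p = 4.28e-18; adjusted p = 0.583 with an estimated correlation). Uqcrc1 of complex III fell by 0.46, Ndufa5 of complex I by 0.44 and Atp5o of the ATP synthase by 0.48. The count of 43 became 9 without HFD_AngII 4, 16 without LFD_control 4, 17 without HFD_AngII 1, 19 without LFD_control 1 and 0 without both HFD_AngII 3 and 4. With the length and GC correction it was 27 and the median was -0.30, with the erythroid list as a covariate it was 26, while without HFD_AngII 3 and 4 the median was -0.36. Genes of mitochondrial DNA had 0 of 7 past the threshold by edgeR, DESeq2 or limma-voom, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and a median of -0.08 (camera adjusted p = 0.63; adjusted p = 0.957 with an estimated correlation), with mt-Nd1 at -0.19 (adjusted p = 0.199).

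Fatty acid uptake and oxidation genes fell in 8 and rose in 1 of 24 (10 and 1 adjusted over the list alone; median -0.20, camera adjusted p = 0.000555; adjusted p = 0.835 with an estimated correlation). Etfb, Echs1 and Etfa fell by 0.57, 0.46 and 0.40, while Cpt1a, the liver form of the enzyme that commits fatty acids to mitochondrial oxidation, rose by 0.44. Its heart and muscle form Cpt1b had a log2 fold change of -0.18 (adjusted p = 0.486). The list had 5 members past the threshold without LFD_control 4 and 0 without both HFD_AngII 3 and 4. Glucose use genes fell in 7 and rose in 1 of 29 (7 and 2 adjusted over the list alone), without passing camera (adjusted p = 0.0804; adjusted p = 0.945 with an estimated correlation). Camera called this list with DESeq2 and without LFD_control 2, HFD_AngII 3 or HFD_AngII 4, with adjusted p from 0.00125 to 0.333 over the alternatives, and 5 members passed without both HFD_AngII 3 and 4. Slc2a4, the insulin-responsive glucose transporter, fell from 452 ± 34.9 to 306 ± 44.8 CPM (log2 fold change -0.56, SE 0.11, adjusted p = 0.00569), and Eno3, Pfkfb1 and Ldhb fell by 1.14, 1.13 and 0.55. Insulin pathway genes went both ways, with 4 higher and 5 lower of 20 (4 and 6 adjusted over the list alone; camera adjusted p = 0.686; adjusted p = 0.957 with an estimated correlation). Igf1 rose by 0.73, and Grb14 and Akt1 fell by 0.57 and 0.45. The insulin list had 5 members past the threshold without LFD_control 1 or LFD_control 4 and 4 without HFD_AngII 4. Lipid synthesis and storage genes fell in 3 of 26 (3 adjusted over the list alone; camera adjusted p = 0.106; adjusted p = 0.583 with an estimated correlation), namely Fasn, Lpl and Dgat2 (a call lost without HFD_AngII 4), with 5 past the threshold without HFD_AngII 2 or in DESeq2. Ketone metabolism genes had 1 higher and 2 lower of 8, with Slc16a7 at -1.43 and Oxct1 at -0.31 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.26; adjusted p = 0.939 with an estimated correlation). The ketone count of 3 was 1 without LFD_control 1, 3 or 4 or HFD_AngII 1, and Oxct1 was lost without each but LFD_control 2 or HFD_AngII 2, with total-count scaling and with the erythroid covariate. PPAR-alpha targets rose in 2 of 16, among them Cpt1a (2 adjusted over the list alone; camera adjusted p = 0.318; adjusted p = 0.957 with an estimated correlation), and Angptl4 (1.77, adjusted p = 0.0678), Pdk4 (1.20, adjusted p = 0.181) and Ucp3 (0.12, adjusted p = 0.634) did not pass. Angptl4 passed in DESeq2, in limma-voom and without LFD_control 3, and Pdk4 in limma-voom and without LFD_control 3. The PPAR-alpha count was 1 without LFD_control 1 or 4 or HFD_AngII 1 or 3, 4 without LFD_control 3 or in limma-voom and 5 in DESeq2, and camera called the list without HFD_AngII 4 (adjusted p = 0.0494, and 0.0494 to 0.618 over the alternatives).

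Cardiac ion channel genes fell in 12 and rose in 2 of 24 (14 and 2 adjusted over the list alone; median -0.37, camera adjusted p = 8.12e-05; adjusted p = 0.361 with an estimated correlation). The potassium channel genes Kcnq1, Kcnj3 and Kcnh2 fell by 0.93, 0.77 and 0.69, and Gja1, the main ventricular connexin, by 0.52. The count of 14 was 7 without HFD_AngII 4, 9 without LFD_control 4 and 4 without both HFD_AngII 3 and 4. Of 22 calcium cycling genes 4 fell and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.83; adjusted p = 0.957 with an estimated correlation), and the list's mean (0.01) and camera's direction (lower) differed in sign. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.38 (SE 0.09, adjusted p = 0.0168), a call lost without LFD_control 1 or HFD_AngII 4, and Pln, Hrc and Cacnb2 fell by 0.49, 0.45 and 0.35 (Cacnb2 not without LFD_control 4). Atp2b4, named after its value was seen, rose by 0.35, a call lost without LFD_control 1, 3 or 4 or HFD_AngII 2, 3 or 4, in limma-voom, with the length and GC correction and with the erythroid covariate. The calcium count of 5 was 3 without LFD_control 1, LFD_control 4 or HFD_AngII 4. Sarcomere genes had 2 higher and 4 lower of 24 (3 and 6 adjusted over the list alone; median -0.04, camera adjusted p = 0.196; adjusted p = 0.957 with an estimated correlation). Tnni3, Tnnt2 and Myl2 fell by 0.66, 0.57 and 0.57 and Des rose by 0.44, a call lost without HFD_AngII 4, where the count of 6 was 3. Camera called the sarcomere list without HFD_AngII 3 (adjusted p = 0.0279, and 0.0134 to 0.581 over the alternatives). Ventricular cardiomyocyte markers fell in 7 of 15 (8 adjusted over the list alone; median -0.33, camera adjusted p = 0.00659; adjusted p = 0.701 with an estimated correlation). That call was lost with the length and GC correction (camera adjusted p = 0.0628, the highest over the alternatives, from 0.000246), and 1 marker passed without both HFD_AngII 3 and 4.

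Platelet genes had the most negative median among the lists past camera. Of 6 tested members 4 fell (4 adjusted over the list alone), with a median of -2.21 (camera adjusted p = 0.000201; adjusted p = 0.575 with an estimated correlation). Ppbp, a chemokine stored in platelets, fell from 9.97 ± 3.42 to 0.608 ± 0.331 CPM (log2 fold change -4.03, SE 0.35, adjusted p = 0.00019). Itga2b, a platelet integrin, fell from 8.04 to 1.46 CPM, and Gp9 and Gp1bb fell by 4.03 and 1.97. All 4 were lower in every HFD_AngII library than in any LFD_control library. With the stricter filter of 5 CPM in 4 libraries, 2 members passed and the median was -1.32. That filter takes genes of low level out of the list, so the change of the median does not show smaller falls. Pf4, named after its value was seen, did not follow, with a log2 fold change of -0.19 (adjusted p = 0.275). Neutrophil markers, another blood cell type, had a median of -2.23 (-1.31 without LFD_control 3) with 0 of 4 above 0 and 1 past the threshold (1 adjusted over the list alone; camera adjusted p = 0.0532; adjusted p = 0.687 with an estimated correlation). Their mean log2 CPM was 1.80 ± 0.93 in LFD_control and 0.41 ± 0.33 in HFD_AngII (SD, n = 4, exact permutation p = 0.0571, 0.163 after Benjamini-Hochberg adjustment over 20 cell type lists). Macrophage and monocyte markers had a median of 0.25 and B and plasma cell markers of 0.32 (-0.09 without HFD_AngII 1). Erythroid genes had a median of -0.97 (-0.36 without LFD_control 3) with 0 of 8 above 0, and 0 of 8 past the threshold by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.338; adjusted p = 0.99 with an estimated correlation), with Hba-a1 at -1.02 (adjusted p = 0.432). Without LFD_control 2 camera called the erythroid list (adjusted p = 0.000338, and 0.000338 to 0.883 over the alternatives) and 1 member passed.

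**Figure D4:**
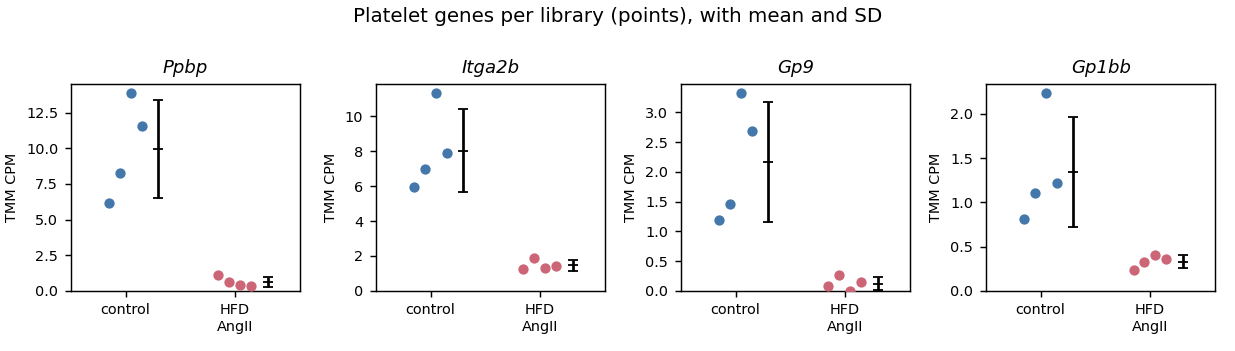
CPM after TMM scaling (vertical axes, each from 0) of 4 platelet genes in the 4 LFD_control (blue) and 4 HFD_AngII (red) libraries, with bars for the mean and SD beside the points. Ppbp fell from 9.97 to 0.608 CPM, and no HFD_AngII library reached the lowest LFD_control library in any of the 4 genes.

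Proliferation genes rose in 7 and fell in 1 of 23 (7 and 1 adjusted over the list alone; median 0.59, camera adjusted p = 0.000555; adjusted p = 0.723 with an estimated correlation). Mki67, the marker of cycling cells, rose from 4.63 to 9.79 CPM (log2 fold change 1.08), and Cdk1, Tpx2 and Kif11 rose by 1.23, 1.22 and 0.98, whereas Cenpf, a kinetochore protein of the same list, fell by 1.83. Mki67 was lost without LFD_control 1, and Tpx2 without HFD_AngII 4. The count of 8 was 3 without LFD_control 1, without both HFD_AngII 3 and 4 or with the stricter filter of 5 CPM in 4 libraries, and 4 without LFD_control 4 or HFD_AngII 4. With that filter the median was 0.20 and the camera call was lost (adjusted p = 0.654, and 1.95e-06 to 0.654 over the alternatives). It takes genes of low level out of the list, so these values do not cover the same members. Macrophage and monocyte markers rose in 4 of 21 (4 adjusted over the list alone; median 0.25, camera adjusted p = 0.0021; adjusted p = 0.701 with an estimated correlation), namely Cx3cr1 by 1.08, Trem2 by 0.78, Mpeg1 by 0.74 and Ms4a7 by 0.73. The macrophage count was 1 without LFD_control 4 or HFD_AngII 4, 2 without LFD_control 1 and 0 without both HFD_AngII 3 and 4, and the list median was 0.16 without LFD_control 4 and 0.38 without LFD_control 3. Trem2 was lost without LFD_control 4 or HFD_AngII 4, Ms4a7 without these or LFD_control 1, and Mpeg1 without these 3 or HFD_AngII 1 or 3 and without a filter on low counts. Interferon-stimulated genes rose in 2 of 30, Rsad2 by 0.61 and Ifih1 by 0.36 (1 adjusted over the list alone; median 0.18, camera adjusted p = 0.0411; adjusted p = 0.957 with an estimated correlation). This camera call was lost without LFD_control 1 (adjusted p = 0.24), LFD_control 3 (0.146), LFD_control 4 (0.162) or HFD_AngII 4 (0.247), with total-count scaling (0.0891), in DESeq2 (0.0818), with the replicate block (0.0527), a surrogate variable (0.0504) or the erythroid covariate (0.274), without both HFD_AngII 3 and 4 (0.19) and without these and LFD_control 1 (0.579). It ran from 1.29e-06 to 0.579 over the alternatives, and the median was 0.10 without LFD_control 1, 0.41 without LFD_control 2 and 0.06 without HFD_AngII 4. Rsad2 was lost without LFD_control 1 or 4, Ifih1 without each library but HFD_AngII 2, in limma-voom, with the length and GC correction, with the atrial or erythroid covariate and with the stricter filter. The count of 2 was 0 without LFD_control 1 or 4, 1 without LFD_control 3 or HFD_AngII 1, 3 or 4, and 10 without LFD_control 2, whose interferon list level was the highest of its group. Cytosolic ribosomal protein genes fell in 8 and rose in 1 of 39 (21 and 1 adjusted over the list alone; median -0.20, camera adjusted p = 1.07e-07; adjusted p = 0.723 with an estimated correlation). Rpl38 fell by 0.32 and Rpl3 rose by 0.34, and the count of 9 was 4 without LFD_control 1, 2 without LFD_control 4 or HFD_AngII 1, 3 or 4, 4 with the length and GC correction, the replicate block or no filter, 5 with the erythroid covariate, and 3 with total-count scaling. Rpl38 was lost with the length and GC correction.

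Among renin-angiotensin genes 2 rose and 2 fell of 18 (2 and 2 adjusted over the list alone; camera adjusted p = 0.902; adjusted p = 0.957 with an estimated correlation). Ace, the angiotensin-converting enzyme, rose by 1.13 (SE 0.16, adjusted p = 0.003) and Agtr1a, the angiotensin II receptor, fell from 39.2 ± 10.1 to 21.8 ± 2.26 CPM (log2 fold change -0.84, SE 0.18, adjusted p = 0.016), a call lost without HFD_AngII 4. Nr3c1 rose by 0.27, a call lost without each library but HFD_AngII 1 or 2, in limma-voom, with the length and GC correction and with the erythroid covariate. Rgs2 fell by 0.38, a call lost without LFD_control 1 or 4 or HFD_AngII 3 or 4 and with total-count scaling. The list count of 4 was 2 without LFD_control 1, LFD_control 4 or HFD_AngII 3 and 1 without HFD_AngII 4. Glp1r, the receptor targeted by liraglutide, had 0 to 3 counts per library and Slc5a1, a sodium-glucose cotransporter, 3 to 13, so no difference in either was detectable at this depth. The incretin and sodium-glucose cotransport list had 0 of 4 tested genes past the threshold by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.955; adjusted p = 0.957 with an estimated correlation), with a median of -0.04 and a mean of 0.07.

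Among the largest rises under the naming rule were those in Cbl (log2 fold change 3.23, SE 0.76, adjusted p = 0.0266), Igfbp2 (2.77), Spp1 (2.52), Mgat5b (2.51), Lmbrd2 (2.43), Tbx15 (2.43), Prkg1 (2.4), Serpinb1c (2.39) and Sprr1a (2.29). Mgat5b, Tbx15 and Serpinb1c passed with each library left out in turn. Cbl was lost without any LFD_control library or HFD_AngII 4, Igfbp2 without each library but HFD_AngII 3, Spp1 without each but LFD_control 2 or HFD_AngII 3, Lmbrd2 without each but HFD_AngII 1 or 2, Prkg1 without any LFD_control library or HFD_AngII 3, and Sprr1a without LFD_control 4 or HFD_AngII 4. Cbl, Lmbrd2 and Prkg1 were also lost in limma-voom, Spp1 and Lmbrd2 with the length and GC correction, Igfbp2 and Lmbrd2 with the erythroid covariate, Igfbp2 with the atrial covariate, Lmbrd2 with a surrogate variable, Spp1 with total-count scaling, and Cbl, Igfbp2, Spp1, Lmbrd2, Prkg1 and Cenpf without a filter on low counts. Cbl was at 8.72 and 5.50 CPM in HFD_AngII 3 and 4 but at 1.0 and 1.77 in HFD_AngII 1 and 2, against 0.445 ± 0.0481 in LFD_control, and Lmbrd2 and Prkg1 were likewise highest in HFD_AngII 3 and 4. Among the largest falls were those in Ppbp (-4.03), Nrgn (-3.17), Inmt (-2.74), Itga2b (-2.44), Lrrc4b (-2.20), Scn10a (-2.15), Mmp9 (-1.91), Cenpf (-1.83) and Stum (-1.66). Inmt was lost without HFD_AngII 3 or HFD_AngII 4, and Cenpf without LFD_control 1 or 4 or HFD_AngII 1, 3 or 4.

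By the annotation, Acta1 lies on the minus strand of chromosome 8 at 123891769 to 123894751, Ankrd1 on the minus strand of chromosome 19 at 36111961 to 36120099 and Col1a1 on the plus strand of chromosome 11 at 94936224 to 94953042. Col3a1 lies on the plus strand of chromosome 1 at 45311538 to 45349706, Postn on the plus strand of chromosome 3 at 54361109 to 54391037 and Ppbp on the plus strand of chromosome 5 at 90768518 to 90770063. Atp2a2 lies on the minus strand of chromosome 5 at 122453513 to 122502225 and Cbl on the minus strand of chromosome 9 at 44142976 to 44234049 (GRCm38).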

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

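Apart from the comparison of the real grouping with other splits, which was planned, the tests weighed in this part were chosen only after the results were seen. A library was singled out where its distance to the nearest other library of its group exceeded Dixon's critical share of the range of the 4. Of 452 groups of values looked at, 21 stood out in this way, against 22.6 given by chance, which singles out about 1 in 20 groups.

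In HFD_AngII 4, Pfkfb1 was at 6.36 CPM, the lowest of its group. In the same library Ccn2 was at 405 CPM, Col4a1 at 1032 and Hbb-bs at 181, each the highest, and the mean log2 CPM of the PPAR-alpha target list was the lowest at 6.12. In LFD_control 1, Ccn2 was at 106 CPM, the lowest. In LFD_control 2, Fasn was at 62.5 CPM and the interferon list at a mean log2 CPM of 4.56, both the highest. In LFD_control 3, Serpinb1c was at 1.74 CPM, the highest, and the Schwann cell and neuron list at 2.01, the lowest. In LFD_control 4, Rpl38 was at 52.3 CPM, Mb at 13019, Cox8b at 481, Tnnt3 at 2.04 and the ribosomal protein list at 7.19, all the highest, and Cd55 at 19.6 CPM, the lowest. In HFD_AngII 1, Tnnt3, a fast skeletal muscle troponin, was at 19.1 CPM, against 1.31 to 3.50 in the other 3. In HFD_AngII 2, Cenpf was at 7.06 CPM and the number of genes with at least 5 counts was 14844, both the highest. In HFD_AngII 3, the angiogenesis list was lowest at 5.0 and the glucocorticoid and fasting list highest at 6.14. Mb and Hbb-bs were named after their values were seen.

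The real grouping gave 2080 genes past the threshold, and the highest of the other splits gave 1. Of the 35 splits of the 8 libraries, 1 reached the real count, the real split itself, which met the planned rule. That is also the smallest share that these 8 libraries can give. The other splits mix the groups, so a true difference widens their spread and keeps their counts low. The comparison therefore cannot exclude chance. It concerns these samples only and does not separate diet from angiotensin II, or either from any other difference between the groups.

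Nuclear respiratory chain genes were lower in HFD_AngII, and the groups also differed in their trend with gene length. With the length and GC correction the difference in the list's mean log2 CPM was -0.30 (SE between libraries 0.08). The list's median log2 fold change moved from -0.36 to -0.30, although 27 genes passed in place of 43. The size of that median argues against the trend as the whole cause. Its camera call stayed with the preset correlation. With an estimated correlation, before the length and GC correction, camera had not called the list (adjusted p = 0.583). A lower share of cardiomyocytes would lower sarcomere genes alike. Of 24 sarcomere genes 14 lay more than 2 SE above the respiratory chain median, a majority, which was the rule for this test. After the correction 12 did, which was not a majority, so the rule was not met there. The genes were counted as if independent. A lower share stays open, since the cardiomyocyte marker median (-0.33) was near that of the respiratory chain and 6 of 15 markers lay more than 2 SE above it. The sarcomere and cardiomyocyte marker lists shared 6 genes. A change per cell under diet and angiotensin II is a hypothesis that was not tested separately.

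Platelet genes were lower in HFD_AngII, which could come from less blood left in the tissue. Neutrophil genes had a median of -2.23 (-1.31 without LFD_control 3) and erythroid genes of -0.97 (-0.36 without LFD_control 3). T and NK cell genes, 3 tested, had -0.34. B and plasma cell genes had 0.32 (-0.09 without HFD_AngII 1), although camera's direction was lower. None of these lists passed camera in the main test. Macrophage and monocyte genes had 0.25. That list passed camera as higher with the preset correlation (adjusted p = 0.0021) but not with an estimated correlation (adjusted p = 0.701). It does not separate cells of the blood from cells of the tissue. With the erythroid list as a covariate the platelet median was -2.07 (median SE 0.28) and 4 genes stayed past the threshold. The erythroid list's mean log2 CPM was 4.29 ± 1.36 in LFD_control and 3.81 ± 0.44 in HFD_AngII (SD, n = 4, exact permutation p = 0.571). A covariate that differs so little between groups could take up little of the platelet fall. A loss of blood in proportion to red cell transcripts therefore stays open. With the length and GC correction the median was -2.14, with 4 genes past the threshold. Clotting during collection, or fewer platelets in the blood or held in the tissue, with or without fewer neutrophils, may each be a source and were not tested. Pf4 (-0.19) did not fall with the others. It was at 16.5 CPM in HFD_AngII, where Tubb1, a platelet gene also named after its value was seen, was at 0.118. The cells that gave the Pf4 reads were not identified, so its level does not bear on platelets alone.

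Interstitial matrix genes were higher in HFD_AngII. If fibroblasts had only become more numerous, fibroblast markers outside the matrix lists would rise as much. The median of these 12 markers was 0.28, lower than that of the matrix list by 0.77 (bootstrap SE 0.18). The bootstrap resampled genes and not libraries. Its SE therefore treats the genes as independent and does not measure the spread between libraries. Of the 12 markers 5 rose and 1 fell. With the length and GC correction the matrix median was 1.0 and the list's camera call stayed with the preset correlation. The difference in the list's mean log2 CPM was then 1.12 (SE between libraries 0.16). With an estimated correlation, before that correction, camera had not called the matrix list (adjusted p = 0.361). More matrix transcript per fibroblast in part of the cells is a candidate explanation that bulk tissue cannot test, and some increase in fibroblast number stays open.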

How the results depend on the processing

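The last 5 settings named in the account of the processing were chosen after seeing the data, and the rest were planned. No gene called in the full data changed sign in any setting, but calls of named genes were lost, as given below. The number of genes past the threshold stayed between 1622 and 2421 over the other scalings, filters, tests and covariates, with 2375 in DESeq2 and 1981 in limma-voom. It was 754 with at least a 1.5-fold change. Leaving out 1 library gave 922 to 2225 genes, 500 to 1172 higher and 422 to 1102 lower. Without both HFD_AngII 3 and 4 it was 325 (195 higher, 130 lower). Without LFD_control 1, HFD_AngII 3 and HFD_AngII 4 it was 123 (84 higher, 39 lower). Distinct list genes past the threshold numbered 247, 137 to 256 with 1 library left out, 69 without HFD_AngII 3 and 4, and 41 without the 3 libraries. Fewer libraries lower the number of calls by themselves, and what else contributed was not tested. The median log2 fold change of the matrix list stayed at 1.11 and 1.03 in the last 2 fits, and that of the respiratory chain list at -0.36 and -0.37.

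Of the genes named in the text, 15 lost their call with the replicate block (Atp2b4, Cd55, Cx3cl1, Dnajc3, Edem1, Hspa5, Hspb8, Ifih1, Lgals3, Mpeg1, Nr3c1, Oxct1, Sel1l, Sprr1a and Timp1). The length and GC correction ended 15 (Atp2b4, Cd55, Cox8b, Dnajc3, Edem1, Hdc, Ifih1, Ighg2c, Lmbrd2, Nr3c1, Pam, Rpl38, Sel1l, Spp1 and Vegfb). Without a filter 10 were lost (Cbl, Cenpf, Gdf15, Igfbp2, Lgals3, Lmbrd2, Mpeg1, Prkg1, Spp1 and Timp1), and with the erythroid covariate 9 (Atp2b4, Hspa5, Ifih1, Igfbp2, Lgals3, Lmbrd2, Nr3c1, Oxct1 and Trib3). Limma-voom ended 7 (Atp2b4, Cbl, Hdc, Ifih1, Lmbrd2, Nr3c1 and Prkg1), the atrial covariate 5 (Edem1, Hdc, Hspa5, Ifih1 and Igfbp2) and total-count scaling 5 (Hspa5, Lgals3, Oxct1, Rgs2 and Spp1). A surrogate variable ended 2 (Lgals3 and Lmbrd2) and the fit without robust=TRUE 2 (Ifih1 and Nr3c1). The stricter filter ended 1 (Ifih1) and left 129 as they were. The remaining named genes did not pass that filter and were not tested with it. Leaving out 1 library ended 5 to 37, the fit without HFD_AngII 3 and 4 81, and that without the 3 libraries 103.

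Some list counts moved in settings not named beside them. With a surrogate variable they were 6 for angiogenesis, 5 for glucocorticoid, PPAR-alpha and lipid synthesis, 4 for heat shock and senescence, 3 for neutrophil, 2 for clock and 1 for vascular endothelial and T and NK cell genes. With the replicate block they were 5 for senescence, 4 for PPAR-alpha, 3 for neutrophil, 2 for unfolded protein and white adipocyte, and 1 for clock and interferon genes. With the erythroid covariate they were 4 for heat shock, 3 for unfolded protein, 2 for glucocorticoid and 1 for clock and interferon genes. With the atrial covariate they were 3 for atrial, Schwann cell and unfolded protein, 2 for glucocorticoid, 1 for interferon and 0 for mast cell genes. Without a filter they were 2 for cytokine, neutrophil, Schwann cell and skeletal muscle and 1 for senescence genes. With total-count scaling they were 2 for cytokine and 1 for vascular endothelial genes. Without robust=TRUE they were 4 for senescence, 2 for neutrophil and glucocorticoid and 1 for clock and interferon genes. With the length and GC correction they were 2 for Schwann cell and skeletal muscle and 1 for interferon genes. The interferon count was also 1 in limma-voom and with the stricter filter, which gave 2 for glucocorticoid genes.

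Camera called 15 lists, 14 to 20 over the other settings with the preset correlation, 0 with an estimated correlation, and fry 9 (directional) and 29 (mixed), which test other hypotheses. Replicate numbers did not pair the samples (r of same-numbered deviations 0.05, -0.08, 0.12 and -0.13), and with the replicate block 1622 genes passed. The block took the respiratory chain count from 43 to 19 and the ribosomal count from 9 to 4. Myh7 changed sign in limma-voom (-0.20), with the replicate block (-0.19), with the erythroid covariate (-0.035), and over left-out libraries (-0.21 to 0.57). Hba-a1 was 0.10 and Hbb-bs 0.13 with the erythroid covariate, and Mb 0.026 with the length and GC correction. Sln ran from -0.78 to 0.30 over left-out libraries and was 0.77 without HFD_AngII 3 and 4 and 0.39 without the 3 libraries. These 5 genes had not passed in the full data. The interferon list's median was -0.0062 without the 3 libraries. The cause was not tested. Depth limits genes of few counts, and a 1.5-fold change was recovered in 56.3% of simulated genes. The simulation changed 200 of 13460 genes per draw, a far smaller share than the 15.5% called in the data. The adjusted p depends on that share, so the recovery in these data may differ.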

Other observations

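The genes named singly in this part were chosen after their values were seen, except those of the fixed lists. Oxidant and antioxidant genes rose in 7 and fell in 1 of 28 (11 and 4 adjusted over the list alone; camera adjusted p = 0.0704; adjusted p = 0.723 with an estimated correlation). Nox4, an oxidase that makes hydrogen peroxide, rose by 0.95 and Srxn1, an antioxidant enzyme, by 0.62, while Maob fell by 0.57. Nox4 was lost without LFD_control 4. The count of 8 was 4 without LFD_control 1, LFD_control 4 or HFD_AngII 4 and 14 in DESeq2, and camera called the list in limma-voom, without a filter, with the length and GC correction and without LFD_control 2 or 3 (adjusted p from 0.00847 to 0.199 over the alternatives). Nitric oxide and cyclic GMP genes rose in 3 and fell in 1 of 20 (3 and 1 adjusted over the list alone; camera adjusted p = 0.26; adjusted p = 0.646 with an estimated correlation), with Npr3, the clearance receptor of natriuretic peptides, up by 0.91, Ddah1 by 0.82 and Pde1c down (-0.79), and 2 past the threshold without both HFD_AngII 3 and 4. Senescence genes rose in 2 of 18, Gdf15 by 1.28 and Igfbp7 by 0.78 (2 adjusted over the list alone; camera adjusted p = 0.248; adjusted p = 0.835 with an estimated correlation). Gdf15 was lost without LFD_control 1, 2 or 4 or HFD_AngII 4 and without a filter on low counts, and the count was 1 without LFD_control 1 or 4, 4 without LFD_control 3 or HFD_AngII 2, 4 in limma-voom and 5 in DESeq2. Emp1 rose from 103 to 237 CPM, Star, which carries cholesterol into mitochondria for steroid synthesis, from 1.97 to 7.12 and Etv4 from 0.963 to 4.61. Esrra, a regulator of mitochondrial genes, fell by 0.36, a call lost without HFD_AngII 4, while Ppargc1a had -0.30 (adjusted p = 0.0996) and passed without LFD_control 2. Tubb1 and Clec1b, further platelet genes outside the list, fell by 4.10 and 2.5.

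Several lists moved little or in both directions. Cytokines and chemokines had 3 higher and 1 lower of 29 (1 and 1 adjusted over the list alone; camera adjusted p = 0.827; adjusted p = 0.957 with an estimated correlation), with Spp1, Lgals3 and Cx3cl1 up by 2.52, 0.64 and 0.49 and Ccl11 down (-1.15), and a median of -0.03 against camera's direction of higher. That count of 4 was 2 without LFD_control 1 or 4 and 1 without HFD_AngII 1 or 4. Spp1 was lost without each library but LFD_control 2 or HFD_AngII 3, Lgals3 without each but LFD_control 2 or HFD_AngII 2, with total-count scaling, a surrogate variable or the erythroid covariate and without a filter, and Cx3cl1 without LFD_control 1, 3 or 4 or HFD_AngII 1 or 4. The unfolded protein list had 4 higher and 1 lower of 25 (4 and 2 adjusted over the list alone; camera adjusted p = 0.686; adjusted p = 0.957 with an estimated correlation), with Trib3 (0.57), Edem1 (0.34), Dnajc3 (0.30) and Sel1l (0.23) higher and Hspa5 (-0.29) lower, 2 past the threshold with the length and GC correction, and 0 past the threshold without LFD_control 1, LFD_control 4 or HFD_AngII 4, 1 without HFD_AngII 1 or 3 and 3 without LFD_control 2. Angiogenesis genes had 1 higher and 2 lower of 27 (1 and 2 adjusted over the list alone; camera adjusted p = 0.83; adjusted p = 0.957 with an estimated correlation), with Ednrb at 0.75, Angpt1 at -0.84 and Vegfb at -0.40, and 1 past the threshold without HFD_AngII 4. Heat shock genes rose in 2 of 17 (3 adjusted over the list alone), with Hspb6 at 0.43 and Hspb8 at 0.33 (1 past the threshold without LFD_control 1 or HFD_AngII 3 or 4, and 4 without LFD_control 3), and camera's direction (higher, adjusted p = 0.83; adjusted p = 0.957 with an estimated correlation) differed from the mean of -0.17. Klf15 was the single member past the threshold of 16 glucocorticoid and fasting genes, at -0.57 (1 adjusted over the list alone; camera adjusted p = 0.958; adjusted p = 0.984 with an estimated correlation), and that list's median was -0.15 (0.28 without LFD_control 3) and its mean 0.09. It had 2 past the threshold without LFD_control 2, 4 without LFD_control 3, 3 without HFD_AngII 3 and 3 in DESeq2 and in limma-voom. Complement rose in 1 of 18, Cd55 by 0.37 (0 adjusted over the list alone; camera adjusted p = 0.196; adjusted p = 0.957 with an estimated correlation), a call lost without each library but LFD_control 3 or HFD_AngII 2 and with the length and GC correction. Without LFD_control 3 the count was 2. Camera called complement genes with the length and GC correction and without LFD_control 3 (adjusted p = 0.0436 and 0.014, and 0.014 to 0.588 over the alternatives). With edgeR, 23 immediate early, 10 MHC class II and 22 circadian clock genes had 0 past the threshold, with 2, 0 and 2 at an unadjusted p under 0.05, 1, 0 and 1 in DESeq2 and 0 in limma-voom (0 adjusted over the list alone; camera adjusted p = 0.371, 0.83 and 0.671; adjusted p = 0.957 with an estimated correlation for each). Without HFD_AngII 3 camera called the immediate early list (adjusted p = 0.00211, and 1e-06 to 0.987 over the alternatives) and 1 member passed, as 1 did without LFD_control 3. The clock list had 2 past the threshold without LFD_control 3 and 1 without HFD_AngII 3, and the MHC class II list 3 with the erythroid covariate.

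Of the other cell type lists, neutrophil markers fell in 1 of 4 (1 adjusted over the list alone), Mmp9, with a median of -2.23, or -1.31 without LFD_control 3 (camera adjusted p = 0.0532; adjusted p = 0.687 with an estimated correlation), and S100a8 had -2.54 (adjusted p = 0.113) and passed in DESeq2 and without LFD_control 1. Camera called the neutrophil list in DESeq2 and without LFD_control 1 or HFD_AngII 4, among other settings (adjusted p from 5.69e-05 to 0.129 over the alternatives), and its count was 2 without LFD_control 1 and 3 in DESeq2. White adipocyte markers fell in 1 of 11, Lpl (1 adjusted over the list alone; median -0.37, or -0.56 without HFD_AngII 2 and -0.25 without HFD_AngII 3; camera adjusted p = 0.0532; adjusted p = 0.701 with an estimated correlation), with 2 past the threshold without HFD_AngII 2. Camera called this list without HFD_AngII 1, 2 or 4, in limma-voom and in other settings (adjusted p from 0.00748 to 0.409 over the alternatives). The next 8 lists each had a camera adjusted p of 0.987, and 0.99 with an estimated correlation. Brown adipocyte markers had 2 higher and 2 lower of 5 (2 and 3 adjusted over the list alone), with Dio2 at 1.56, Cidea at 0.55, Cox8b at -0.49 and Kcnk3 at -0.40, a median of -0.30 and a mean of 0.18, and 2 past the threshold without HFD_AngII 4. The mean log2 CPM of these markers was 6.09 in LFD_control and 6.28 in HFD_AngII. The cells that gave these reads were not identified, so the list does not bear on brown adipocytes alone. Mast cell markers rose in 1 of 6, Hdc by 0.93 (1 adjusted over the list alone), a call lost without each library but LFD_control 3 or HFD_AngII 2, in limma-voom, with the length and GC correction and with the atrial covariate, with a median of -0.16 and a mean of 0.01. B and plasma cell markers fell in 1 of 7, Ighg2c at -0.44 (1 adjusted over the list alone), with a median of 0.32 (-0.09 without HFD_AngII 1) although camera's direction was lower, and that call was lost with the length and GC correction. Atrial markers rose in 1 of 11, Pam by 0.50 (1 adjusted over the list alone), a call lost without LFD_control 1 or 4 and with the length and GC correction, with a median of -0.01, a mean of 0.15 and 2 past the threshold without HFD_AngII 1. Pericyte and smooth muscle markers had 1 higher and 1 lower of 16, Des and Abcc9 (2 and 1 adjusted over the list alone), and 1 without HFD_AngII 4. Skeletal muscle markers had 1 lower of 9, Cacna1s at -0.71 (1 adjusted over the list alone), and 2 past the threshold without HFD_AngII 1 and in DESeq2. Without LFD_control 1 and HFD_AngII 3 and 4, camera called the atrial list (adjusted p = 0.0301, and 0.0301 to 0.995 over the alternatives) and the pericyte list (adjusted p = 0.0239, and 0.0239 to 0.995).

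Vascular endothelial markers had 0 of 17 and lymphatic endothelial markers 0 of 7 past the threshold by edgeR (0 adjusted over the list alone), with 1 each at an unadjusted p under 0.05, 1 and 0 in DESeq2 and 0 in limma-voom. The vascular list had 1 past the threshold without LFD_control 4 and the lymphatic list 1 without LFD_control 2. T and NK cell markers had 0 of 3 (camera adjusted p = 0.338; adjusted p = 0.701 with an estimated correlation) and epicardial markers 0 of 8 (camera adjusted p = 0.468; adjusted p = 0.753 with an estimated correlation) by edgeR, DESeq2 or limma-voom, with 1 each at an unadjusted p under 0.05 and 0 adjusted over the list alone, and each had 1 past the threshold without LFD_control 3. Schwann cell and neuron markers rose in 1 of 9, Pmp22 by 0.46 (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.289; adjusted p = 0.869 with an estimated correlation). Without HFD_AngII 1 that list had 3 past the threshold and a camera adjusted p of 0.0382 (0.0382 to 0.966 over the alternatives). Conduction and valve markers fell in 1 of 10, Irx3 at -0.47 (1 adjusted over the list alone; camera adjusted p = 0.684; adjusted p = 0.99 with an estimated correlation).

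Among the calls of single genes in this part, Trib3 was lost without LFD_control 1, 2 or 4 or HFD_AngII 2, 3 or 4, Edem1 without each library but LFD_control 3 or HFD_AngII 2, Dnajc3 without LFD_control 1, 2 or 4 or HFD_AngII 1 or 4, Sel1l without LFD_control 1 or 4 or HFD_AngII 1, 3 or 4, and Hspa5 without each library but LFD_control 2. Angpt1 was lost without LFD_control 4 or HFD_AngII 4, Vegfb and Cox8b without these or HFD_AngII 1, Kcnk3 and Des without HFD_AngII 4, and Hspb8 without LFD_control 1 or HFD_AngII 3 or 4. Edem1, Dnajc3, Sel1l, Vegfb and Cox8b were also lost with the length and GC correction, Trib3 and Hspa5 with the erythroid covariate, Edem1 and Hspa5 with the atrial covariate, and Hspa5 with total-count scaling.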
